A study of Mus musculus with 20 samples.

How the data were processed

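RNA was taken from the livers of 20 mouse fetuses at stage E17.5, 4 in each of 5 groups, from dams fasted for 24 h. Per the labels' protocols, RNA was extracted with Trizol and a column, libraries were made with a stranded poly(A) mRNA kit, and single reads of 75 nucleotides were sequenced. Per the submitters' processing notes, bcl2fastq 2.17.1.14 and Partek 7.0 were used with the mouse genome build GRCm38.p6. The table that the authors deposited holds log2 values for 45802 gene entries in 20 libraries. Every library has the same quantiles over the values present, so quantile normalization had been applied before the values were deposited. The quantity before the logarithm is not named. The aligner, the counting rule and its use of strand are not given in the sources used here. Blank cells were read as no value: 10591 genes had no value in any library, 17345 had one in every library, and 173 of the tested genes had a blank in at least 1. The values cannot be taken back to reads, so the depth of the libraries is unknown and a count test was not run. What precision the depth gives to a low value therefore cannot be stated. Pairs of libraries correlated at 0.907 to 0.986 across genes, and none were duplicates. Gene names were those of the table, of which 41223 of 45802 matched a RefSeq symbol (11234 of 11807 tested), and gene positions came from the RefSeq annotation of GRCm38.p6.

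Groups and fetal sex were taken from the labels. Litter was read from a number in the sample descriptions that no label explains, so littermates are presumed. KODam_HetFetus replicates 1 and 2, KODam_KOFetus replicates 1 and 2, and FloxDam_FloxFetus replicates 3 and 4 share such a number, and the other fetuses have numbers of their own. Deviations from the group mean correlated at 0.212, -0.0925 and 0.323 within these pairs, against at most 0.296, 0.185 and 0.141 for other pairs of the same groups. Since a split of 4 libraries into pairs makes both pairs correlate, these values do not settle which fetuses are alike. The consensus correlation of littermates in the fit with litter as a block was 0.568. The main fit counts each fetus as independent, although KODam_HetFetus, KODam_KOFetus and FloxDam_FloxFetus each hold 3 presumed litters. Its p-values therefore do not separate the spread between litters from that between fetuses. The comparisons, the gene lists and the alternatives not named as added were chosen before the data were examined, and the tests that weigh explanations were chosen after.

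A gene was tested where its linear value was at least 1 in at least 4 libraries, which left 11807. All 20 libraries entered one fit with a mean per group, using limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend, 15 residual and 4.09 prior degrees of freedom). Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with calls at an adjusted p under 0.05. There were 7 comparisons: the maternal Ppara knockout (KODam_HetFetus minus HetDam_HetFetus), the fetal Ppara knockout (KODam_KOFetus minus KODam_HetFetus), both (KODam_KOFetus minus HetDam_HetFetus), the maternal liver Cpt2 knockout (Cpt2LKODam_FloxFetus minus FloxDam_FloxFetus), the difference of the maternal effects, the control groups (HetDam_HetFetus minus FloxDam_FloxFetus), and males minus females. Fold changes of genes with low values depend on the scale, which was tried with pseudocounts of 0.1 and 4 on the linear values.

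The named genes were Ppara and Cpt2, a fixed panel of 12 genes, per comparison the 8 largest rises and 8 largest falls (5 and 5 for the control groups, the difference and sex) among called genes with a curated symbol whose libraries did not overlap between groups, up to 4 called members with the smallest p from each list described, and where fewer than 5 genes were called also the 5 with the smallest p. The text gives part of these, and some named genes are not reported here. Fgf21, of the panel, and Uty did not reach the minimum. Of 38 fixed gene lists, 35 had at least 5 tested members and were tested with camera (preset correlation 0.01), with an estimated correlation, and with fry. Adjusted p-values of lists are over the lists of a comparison. The lists called with the preset correlation numbered 14, 13, 22, 7, 14, 17 and 12 in the order of the comparisons above, and with an estimated correlation 0, 5, 0, 0, 0, 0 and 0. The correlation of the maternal effects was tested with 100 relabellings of the libraries.

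The limma step was tested on simulated data for 11634 genes with 50 changed genes per size. For the maternal Ppara knockout it recovered 20%, 80%, 92% and 100% of changes of 0.5, 1, 2 and 4 on the log2 scale, with 12 false calls among 158. For the fetal knockout it recovered 22%, 74%, 92% and 100% (2 false among 146), and for the maternal Cpt2 knockout 18%, 78%, 94% and 100% (7 false among 152). The simulation drew independent normal noise for each gene and library, without correlation between littermates or between genes. These rates therefore need not hold for the real libraries.

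The replicate numbers of the labels were checked for pairing by correlating the deviations of same-numbered libraries. All 4 pairs exceeded 0.1 only between the control groups (0.127 to 0.323), where the fit with a replicate block called 15 genes against 16 without it. Alternatives tried were other filters, pseudocounts, scalings between libraries, trend settings, fetal sex as a covariate, the litter as a block or averaged, the replicate block, only the groups compared, and each library left out in turn. After the data were seen, 3 alternatives were added for every count: leaving out 4 libraries with marker transcripts of neighbouring tissues (HetDam_HetFetus replicates 1 and 4, KODam_KOFetus replicate 2 and Cpt2LKODam_FloxFetus replicate 2), leaving out KODam_HetFetus replicates 1 and 2, and adding the number of genes with a value as a covariate. Trimmed-mean scaling was also added for the correlation of the maternal effects. Tables were handled with the package data.table (version 1.17.8), the litter block used statmod 1.5.0, and figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.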

Results

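Bulk RNA sequencing measured gene expression in the livers of 20 mouse fetuses at stage E17.5, all labelled as C57BL/6, after their dams had been fasted for 24 h. The fetuses formed 5 groups of 4, each with 2 females and 2 males. In the Ppara arm, heterozygous fetuses of heterozygous dams (HetDam_HetFetus) were set against heterozygous fetuses of knockout dams (KODam_HetFetus) and knockout fetuses of knockout dams (KODam_KOFetus). Ppara encodes PPARA, the nuclear receptor that switches on fatty acid oxidation and ketone body genes in the fasted liver. In the Cpt2 arm, fetuses of dams that lack Cpt2 in the liver (Cpt2LKODam_FloxFetus) were set against fetuses of floxed dams without the deletion (FloxDam_FloxFetus). Cpt2 encodes the inner mitochondrial carnitine palmitoyltransferase, which long-chain fatty acids need for beta-oxidation. The design text of the series and the titles of the Cpt2 arm speak of wild-type fetuses and dams where the genotype labels say heterozygous or floxed, and the groups here follow the genotype labels. Values were log2 expression, so differences between groups are log2 fold changes, given with their standard error and n = 4 libraries per group unless stated otherwise. The read depth of the libraries is unknown. The number of genes with a value ran from 23334 to 26255 per library, and its mean was lowest in HetDam_HetFetus, at 24154 ± 624 (SD, n = 4), against 24961 ± 951 in KODam_HetFetus and 25317 ± 638 in FloxDam_FloxFetus.

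The targeted genes were examined first. Ppara (chromosome 15, 85734910 to 85806851, GRCm38.p6, protein-coding) stood at a log2 value of 3.13 ± 0.281 (SD, n = 4) in HetDam_HetFetus, 2.56 ± 0.679 in KODam_HetFetus, 2.26 ± 0.27 in KODam_KOFetus, 3.31 ± 0.45 in FloxDam_FloxFetus and 3.35 ± 0.0812 in Cpt2LKODam_FloxFetus. Its single libraries spanned 2.86 to 3.47, 1.82 to 3.22, 1.87 to 2.48, 2.88 to 3.71 and 3.27 to 3.44 in the same order. Ppara was lower in KODam_KOFetus than in HetDam_HetFetus (log2 fold change -0.87 ± 0.264, limma adjusted p = 0.0237), while knockout and heterozygous fetuses of knockout dams differed by -0.30 ± 0.264 (adjusted p = 0.682). The first of these calls was lost without HetDam_HetFetus replicate 3 (-0.75, adjusted p = 0.0703) or 4 (-0.83, adjusted p = 0.0557), or KODam_KOFetus replicate 3 (-0.74, adjusted p = 0.0743) or 4 (-0.88, adjusted p = 0.0501). Transcript remained in every knockout library, and whether its reads fall inside the deleted part of the gene is not known, so these values do not check the genotype labels. Cpt2 (chromosome 4, 107903982 to 107923589, GRCm38.p6) was deleted in the livers of the dams and not in the fetuses. Fetal Cpt2 stood at 4.00 ± 0.309 (SD, n = 4) in FloxDam_FloxFetus and 3.90 ± 0.0534 in Cpt2LKODam_FloxFetus, a difference of -0.10 with an adjusted p of 0.849. In the Ppara arm it stood at 3.85 ± 0.174, 4.00 ± 0.327 and 3.30 ± 0.198 in HetDam_HetFetus, KODam_HetFetus and KODam_KOFetus.

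Loss of Ppara in the dam was assessed in heterozygous fetuses, which keep a working allele of their own. Several PPARA target genes rose in the livers of fetuses of knockout dams. Ehhadh (chromosome 16, 21761285 to 21787834, GRCm38.p6), the peroxisomal bifunctional enzyme of fatty acid oxidation, rose by 3.45 ± 0.262 on the log2 scale (limma adjusted p = 5.92e-07), from 3.74 ± 0.203 (SD, n = 4) to 7.19 ± 0.348. Pdk4, the kinase that holds back pyruvate oxidation, rose by 2.44 ± 0.389 (adjusted p = 2.72e-04), and Angptl4, an inhibitor of lipoprotein lipase, by 1.61 ± 0.23 (adjusted p = 1.49e-04). The acyl-CoA thioesterase genes Acot2 and Acot1 rose by 3.01 ± 0.377 and 2.06 ± 0.281, and the lipid droplet genes Cidec and Plin2 (its tested entry of 2, Plin2_2) by 3.13 ± 0.751 and 1.80 ± 0.232. Ehhadh in replicate 4 (7.71) and Pdk4 in replicate 3 (5.79) of KODam_HetFetus, and Acot1 and Acot2 in replicate 4 of HetDam_HetFetus (3.03 and 0.79), stood apart from the other libraries of their groups. Of all 11800 tested genes, 3117 rose and 1483 fell. Of 44 canonical PPARA targets tested, 15 rose, 2 fell and 27 did not pass the test. Adjusted over the list alone, 15 rose and 3 fell. The falls numbered 7 after trimmed-mean scaling and 4 after quantile normalization, with 15 rises in each, and the median of 0.33 was 0.20 after the former and 0.60 without replicates 1 and 2 of KODam_HetFetus, where 0 fell. As a set these targets passed with fry (adjusted p = 0.00671) and not with camera (adjusted p = 0.0643, adjusted p = 0.732 with an estimated correlation). Members without a call included Cpt1a (0.45, adjusted p = 0.402), the outer mitochondrial carnitine palmitoyltransferase of liver, and Vnn1 (0.13, adjusted p = 0.73). Cyp4a10 and Cyp4a14, of the fixed panel, had no call either, and the difference of Cyp4a10 was negative. The panel gene Acadm was called lower. Its call was lost without replicates 1 and 2 of KODam_HetFetus (-0.24, limma adjusted p = 0.373) and without HetDam_HetFetus replicate 4 (-0.51, limma adjusted p = 0.0547).

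Genes of bile acid handling and of hepatocyte function were lower in the same fetuses. Cyp7a1 (chromosome 4, 6265612 to 6275632, GRCm38.p6), the rate-limiting enzyme of bile acid synthesis, fell by 3.96 ± 1.05 on the log2 scale (limma adjusted p = 0.00668). Slc10a1, the main bile acid uptake carrier, and Slco1b2, an organic anion uptake carrier, fell by 2.70 ± 0.594 and 2.61 ± 0.682, whereas Abcb4, which exports phospholipid into bile, rose by 0.55 ± 0.143. Of 12 tested genes of bile acid synthesis and transport, 8 fell and 1 rose, and the counts adjusted over the list alone were also 8 and 1 (camera adjusted p = 0.00202, adjusted p = 0.732 with an estimated correlation). Of 34 hepatocyte genes, 12 fell and 1 rose, with the counts adjusted over the list alone again 12 and 1 (camera adjusted p = 1.67e-06, adjusted p = 0.732 with an estimated correlation). They included Cebpa, a transcription factor of hepatocytes and myeloid cells (-1.88 ± 0.287, adjusted p = 2.06e-04). Several of these falls depended on a presumed pair of littermates, replicates 1 and 2 of KODam_HetFetus. Cyp7a1 stood at -3.16 and -4.83 in these littermates, at 0.66 and 1.07 in the other fetuses of the group and at 2.39 ± 0.172 (SD, n = 4) in HetDam_HetFetus. Without the pair, Cyp7a1 (-1.53, adjusted p = 0.2), Slc10a1 (-1.59, adjusted p = 0.0657) and Slco1b2 (-1.66, adjusted p = 0.113) lost their calls, the bile acid list held 0 lower calls at a median of -0.64, and the hepatocyte list held 3 at a median of -0.17. Without 4 libraries that carried marker transcripts of neighbouring tissues, the lower calls numbered 4 for the bile acid list and 6 for the hepatocyte list. Of 40 named genes called for the maternal knockout, 30 were called without the pair.

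Blood cell and proliferation genes moved as well. Of 23 neutrophil and myeloid progenitor genes 19 fell and 0 rose, and 20 fell when adjusted over the list alone (camera adjusted p = 5.39e-11, adjusted p = 0.732 with an estimated correlation). Among them were Mmp8, the neutrophil collagenase (-2.35 ± 0.336, adjusted p = 1.49e-04), and Csf3r, the receptor for granulocyte colony-stimulating factor (-1.02 ± 0.185, adjusted p = 5.60e-04). Camera also called the B lymphoid (median -0.408), megakaryocyte and platelet (-0.222) and macrophage (-0.184) lists lower, but not the erythroid list. Single libraries left out gave medians of -0.56 to -0.288, -0.4 to -0.0961 and -0.272 to -0.107. With an estimated correlation none of these lists was called. Of 32 cell cycle genes 26 rose and 0 fell, and 28 rose when adjusted over the list alone (camera adjusted p = 7.97e-07, adjusted p = 0.732 with an estimated correlation). Ccne1, the cyclin of S-phase entry, rose by 1.30 ± 0.203 and Cdk1, the mitotic kinase, by 0.93 ± 0.143. Of 17 glucocorticoid response genes 8 rose and 1 fell, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0441, adjusted p = 0.732 with an estimated correlation). Sgk1, a serum- and glucocorticoid-induced kinase, rose by 1.92 ± 0.318 and the clock gene Per1 by 1.54 ± 0.339, while Lcn2, an iron-carrier-binding protein, fell by 0.96. Without the littermate pair Lcn2 lost its call (-0.70, adjusted p = 0.0689), and the neutrophil list held 7 lower calls, the cell cycle list 9 higher at a median of 0.39 (0.67 with the pair) and the glucocorticoid list 4 higher. The glucocorticoid list held 5 higher calls after trimmed-mean scaling and without replicate 1 of either group, and 3 without the 4 libraries with marker transcripts of other tissues. Other large rises were those of Crtam (3.81), Wfikkn1 (3.54) and Insc (2.65), and other large falls those of Etnppl (-4.76 ± 0.686, adjusted p = 1.53e-04), an enzyme of phosphoethanolamine breakdown, Keg1 (-4.57) and Hsd17b6 (-3.81). Cyp2c69 fell by 4.81.

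In all, 4600 of 11800 genes (39.0%) changed with the maternal Ppara knockout at a limma adjusted p under 0.05, 3117 up and 1483 down, and 636 of the rises and 536 of the falls were at least 2-fold. The count was 2845 without the littermate pair, 3766 with litter as a random block, and 3173 without the 4 libraries with marker transcripts of other tissues. The share of rises moved with the scaling: the median of all tested genes was 0.144 as deposited and 0.0168 after trimmed-mean scaling, which gave 2212 rises and 2232 falls (49.8% up against 67.8%), and quantile normalization of the tested genes gave 2452 and 2003 (55%). Centring removes a shift of the median whatever its source. These values therefore do not tell a real excess of rises from an excess due to scaling. No list described here changed the sign of its median under either scaling. Acot1 and Acot2, Cyp4a10 and Cyp4a14, and the Cyp2c genes have near-identical copies, so the split of reads among them is uncertain.

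**Figure D1:**
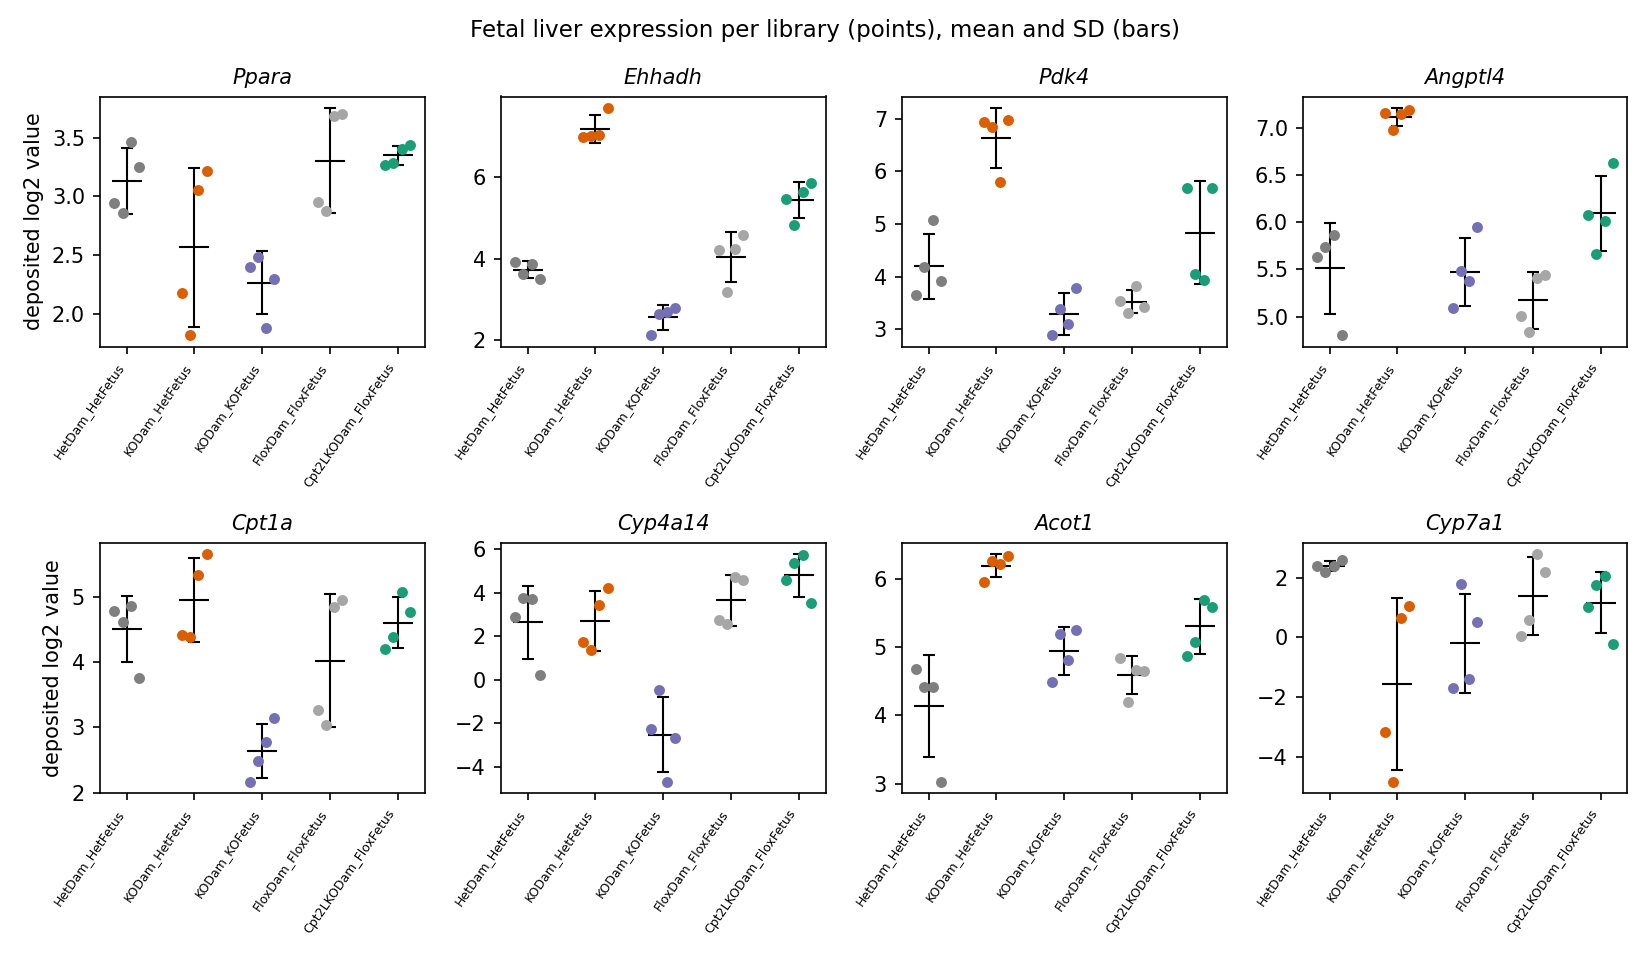
Deposited log2 values (y axes, separate scales that do not start at 0) of 8 genes in the 5 groups, with 1 point per fetal liver library and bars for the mean and SD of 4. Ehhadh is highest in KODam_HetFetus (7.19 ± 0.348) and lowest in KODam_KOFetus (2.56 ± 0.299), and Cyp7a1 spreads widely within KODam_HetFetus.

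Loss of the fetus's own Ppara was assessed between knockout and heterozygous fetuses of knockout dams. These groups share no presumed litter, so fetal genotype cannot be separated from differences between their dams and litters. Fatty acid oxidation genes fell in the knockout fetuses. Cyp4a10 (chromosome 4, 115518287 to 115533649, GRCm38.p6) and Cyp4a14 (chromosome 4, 115486200 to 115496158), the microsomal fatty acid omega-hydroxylases, fell by 6.14 ± 0.861 (3 knockout libraries with a value) and 5.22 ± 0.889 on the log2 scale (limma adjusted p = 4.49e-04 and 0.00263). Ehhadh fell by 4.63 ± 0.262 (adjusted p = 1.66e-09) and Cpt1a by 2.31 ± 0.406 (adjusted p = 0.0035). Of the 44 canonical PPARA targets 24 fell and 0 rose, or 30 and 1 adjusted over the list alone (camera adjusted p = 2.70e-45, adjusted p = 5.51e-04 with an estimated correlation). Further falls were those of Acaa1b (-4.46 ± 0.288), the peroxisomal thiolase, of Slc25a34 (-4.63 ± 0.812, 3 knockout libraries with a value), a mitochondrial carrier, and of Pdk4 (-3.35 ± 0.389), Cidec (-4.12 ± 0.751) and Angptl4 (-1.65).

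Mitochondrial, peroxisomal, ketone body and lipid droplet genes fell as sets. Of 23 mitochondrial fatty acid oxidation genes 12 fell and 0 rose, and 19 fell when adjusted over the list alone (camera adjusted p = 3.07e-30, adjusted p = 0.0217 with an estimated correlation). Acadvl, the very-long-chain acyl-CoA dehydrogenase, fell by 1.79 ± 0.142 (limma adjusted p = 1.95e-07), whereas Acadm, the medium-chain dehydrogenase, was not called (-0.67, adjusted p = 0.141). Of 23 peroxisomal and microsomal fatty acid oxidation genes 13 fell and 0 rose, and 19 fell when adjusted over the list alone (camera adjusted p = 3.84e-33, adjusted p = 0.00729 with an estimated correlation). Ech1, an auxiliary enzyme for unsaturated chains, fell by 2.05 ± 0.129 (adjusted p = 5.70e-09). Of 9 ketone body genes 2 fell, or 5 adjusted over the list alone (camera adjusted p = 4.04e-05, adjusted p = 0.0241 with an estimated correlation), and of 18 lipid droplet genes 4 fell, or 6 adjusted over the list alone (camera adjusted p = 6.70e-04, adjusted p = 0.0111 with an estimated correlation). The ketone body falls numbered 4 after trimmed-mean scaling and 4 without replicates 1 and 2 of KODam_HetFetus, where the lipid droplet median went from -0.26 to -0.44, and 1 without the 4 libraries with marker transcripts of other tissues and without any one of KODam_HetFetus replicates 2, 3 and 4 and KODam_KOFetus replicates 1 and 4. The lipid droplet median was -0.11 without KODam_KOFetus replicate 1. Plin5, the droplet coat protein of oxidative tissues, fell by 2.69 ± 0.444. KODam_KOFetus replicate 2, which carried skeletal muscle transcripts, stood above the other libraries of its group for Plin5 (1.89 against 0.25) and for the means of the peroxisomal and lipid droplet lists. No hepatocyte or bile acid gene of the lists was called here, with list medians of 0.04 and 0.10. In all 97 of 11805 genes were called, 94 lower and 3 higher. The 3 were Clec4a1 (1.17), Ank (1.05) and Hmox1 (0.51), and 0 genes were called higher with litter as a random block, where 71 fell. Leaving out KODam_HetFetus replicate 2 alone ended the calls of Clec4a1 (adjusted p = 0.0581), Ank (0.125) and Hmox1 (0.0694), leaving out its replicate 1 those of Clec4a1 (0.0558) and Ank (0.111), and leaving out KODam_KOFetus replicate 1 those of Ank (0.211) and Hmox1 (0.0773). Ank also lost its call without KODam_HetFetus replicate 3 or 4 or KODam_KOFetus replicate 2 or 4 (adjusted p 0.052 to 0.158). Leaving out KODam_KOFetus replicate 3 gave 147 calls, 50 higher and 97 lower, and fitting only these groups gave 63. With a pseudocount of 4, Cyp4a10, Cyp4a14 and Slc25a34 lost their calls.

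Knockout fetuses of knockout dams were also compared with heterozygous fetuses of heterozygous dams, and fatty acid oxidation genes were lower in the knockout fetuses. Cyp4a10 fell by 8.07 ± 0.861 on the log2 scale (3 knockout libraries with a value, limma adjusted p = 2.10e-05), Adtrp, a lipid ester hydrolase, by 4.41 ± 0.509 (adjusted p = 3.54e-05), and Ehhadh by 1.18. Pdk4 (-0.91, adjusted p = 0.0909), Angptl4 (-0.04, adjusted p = 0.927) and Plin2_2 (0.11, adjusted p = 0.766) were not called. Of 23 mitochondrial fatty acid oxidation genes 18 fell and 0 rose, or 19 adjusted over the list alone (camera adjusted p = 7.95e-17, adjusted p = 0.11 with an estimated correlation). Of the peroxisomal and microsomal genes 17 of 23 fell and 1 rose, or 19 and 1 adjusted over the list alone (camera adjusted p = 7.05e-16, adjusted p = 0.0861 with an estimated correlation). Of the 44 canonical targets 24 fell and 3 rose, or 25 and 5 adjusted over the list alone (camera adjusted p = 1.12e-12, adjusted p = 0.0861 with an estimated correlation), and 1 rose without the 4 libraries with marker transcripts of other tissues, without HetDam_HetFetus replicate 4 and without KODam_KOFetus replicate 2. Of 33 erythroid genes, which mark the red cell precursors that fill the fetal liver, 11 rose, 0 fell and 22 did not pass, or 12 rose adjusted over the list alone (camera adjusted p = 0.00128, adjusted p = 0.537 with an estimated correlation). The rises numbered 7 after trimmed-mean scaling, without the 4 libraries with marker transcripts of other tissues, and without HetDam_HetFetus replicate 2 or 4 or KODam_KOFetus replicate 4, and their median of 0.49 was 0.32 without KODam_KOFetus replicate 1. Of 34 hepatocyte genes 8 fell and 1 rose, with the same counts adjusted over the list alone (median -0.43, camera adjusted p = 1.05e-07, adjusted p = 0.438 with an estimated correlation). The falls numbered 13 after trimmed-mean scaling, 3 without the 4 libraries and 2 to 10 with single libraries left out, each of which moved it (2 without KODam_KOFetus replicate 1). Among the erythroid genes were the erythropoietin receptor gene Epor (0.93 ± 0.178) and Fech, the last enzyme of heme synthesis (0.73). Other rises were those of Rdh9 (3.13), Timp1 (2.55), an inhibitor of matrix proteases, and Tnfrsf12a (2.53).

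The combined comparison called 2916 of 11801 genes (24.7%), 2053 higher and 863 lower. Leaving out KODam_KOFetus replicate 4 gave 1828, and leaving out the 4 libraries with marker transcripts of other tissues gave 1757. With litter as a random block the count was 2320. The share of rises, 70.4% as deposited, was 55.9% after quantile normalization and 45.4% after trimmed-mean scaling. Of the 94 genes that fell with the fetal knockout, 68 also fell in the combined comparison (6.875 expected for independent lists). With the maternal knockout 36 of them rose (24.83 expected) and 4 fell (11.81 expected). Both comparisons share libraries with the fetal comparison. Across 11634 genes the maternal and fetal effects correlated at r = -0.517. Unchanged groups drawn from the shuffled residuals of all 20 libraries, with KODam_HetFetus shared, gave -0.535, and splitting the real KODam_HetFetus libraries gave -0.349. The covariance of these effects was -0.127 against a simulated -0.0386, a difference of -0.0881. The draws pool the spread of all groups and ignore litters, so they may understate the covariance that comes from sharing the KODam_HetFetus libraries. The maternal and combined effects correlated at 0.826 (simulated 0.4, controls split 0.657), with a covariance of 0.308 against 0.0269, a difference of 0.281. They shared 1820 rises (542 expected for independent lists) and 626 falls (108.5 expected), and part of these excesses may come from the shared libraries. Genes are not independent replicates.

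**Figure D2:**
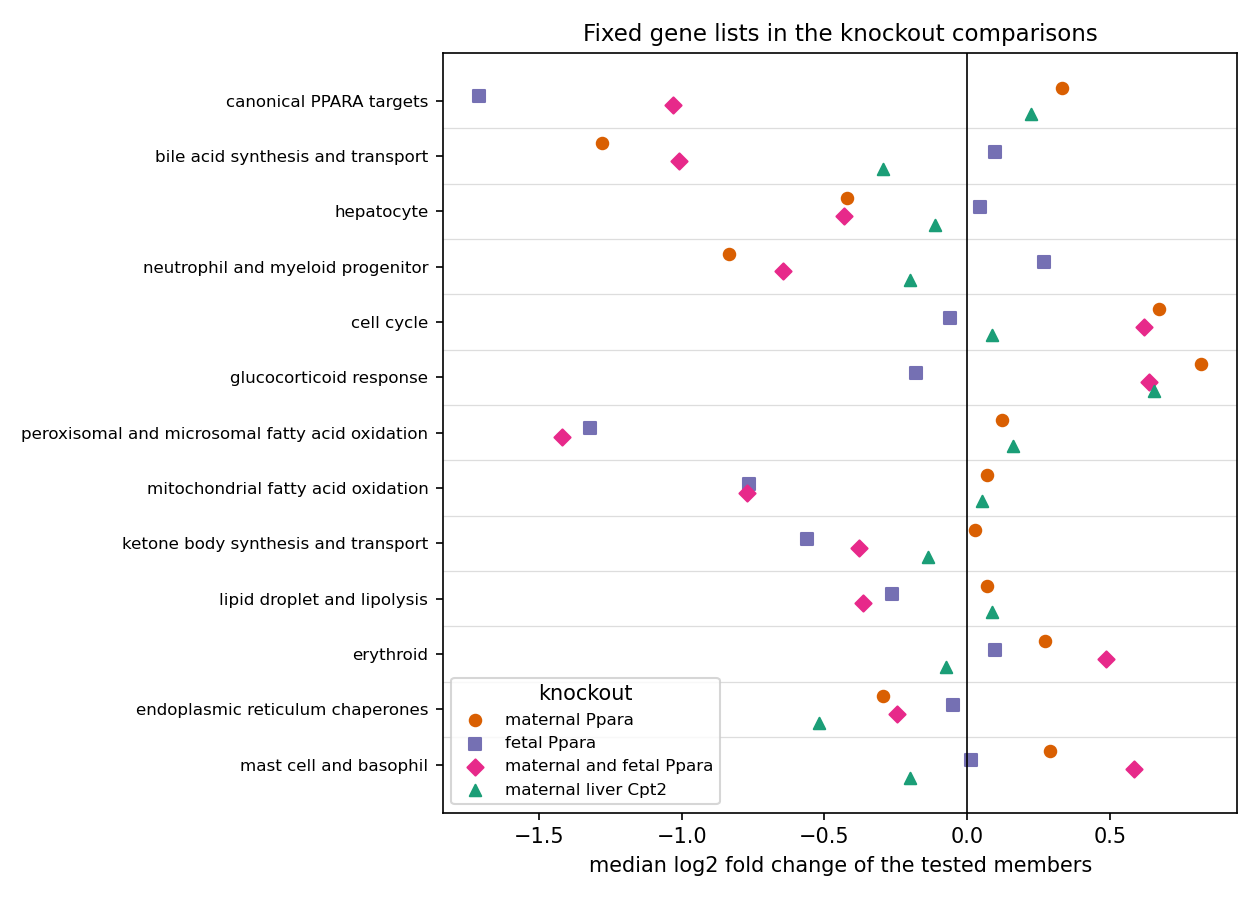
Median log2 fold change (x axis) of the tested members of 13 gene lists (y axis) in the 4 knockout comparisons, each with its own symbol. Canonical PPARA targets have a median of -1.71 for the fetal knockout and 0.33 for the maternal knockout, and the bile acid list has a median of -1.28 for the maternal knockout.

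Loss of Cpt2 in the maternal liver, which removes long-chain fatty acid oxidation there, was assessed in fetuses that differed by this maternal genotype, and no gene passed the test. The log2 fold change was 1.40 ± 0.262 for Ehhadh (limma adjusted p = 0.166), 1.31 ± 0.389 for Pdk4 (adjusted p = 0.346) and 0.92 for Angptl4 (adjusted p = 0.321). Fgfr2 (chromosome 7, 130162451 to 130266808, GRCm38.p6), a fibroblast growth factor receptor gene, had the smallest p, with a difference of -1.17 ± 0.2 (adjusted p = 0.147). The limma test called 0 of 11805 genes, with 1311 at an unadjusted p under 0.05 where chance gives 590. That number was 617 without Cpt2LKODam_FloxFetus replicate 4, and 912 to 1596 without any other single library. Most of the excess thus depended on that 1 library. Among the gene lists, all 16 endoplasmic reticulum chaperone genes had negative differences, with a median of -0.52. None was called over all genes and 11 were lower adjusted over the list alone (camera adjusted p = 3.24e-12, adjusted p = 0.334 with an estimated correlation). Calr (-0.65 ± 0.159), a calcium-binding chaperone, and Hspa5 (-0.64 ± 0.19), the main Hsp70 chaperone of the compartment, were picked as examples after their values were seen. Of 17 glucocorticoid response genes 16 had positive differences, with a median of 0.65, 0 called over all genes and 2 adjusted over the list alone (camera adjusted p = 8.66e-07, adjusted p = 0.494 with an estimated correlation). The canonical PPARA targets had a median of 0.22 with 31 of 44 positive, 0 called over all genes and 5 higher adjusted over the list alone (camera adjusted p = 6.55e-05, adjusted p = 0.836 with an estimated correlation). Without Cpt2LKODam_FloxFetus replicate 4 the difference of Ehhadh was 1.27 (adjusted p = 0.569) and the glucocorticoid median was 0.42. Single genes crossed the threshold without that library and without FloxDam_FloxFetus replicate 1 (1 call each).

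The responses to the maternal knockouts of Ppara and Cpt2, which share no library, were then compared. Across 11634 genes their log2 fold changes correlated at r = 0.628 (Spearman rho 0.622), and 71.3% had the same sign. Of 100 relabellings of the libraries within each arm, 2 gave an absolute r as large (two-sided permutation p = 0.0297), with a highest absolute value of 0.685. Leaving out Cpt2LKODam_FloxFetus replicate 4 lowered r to 0.421, and the other libraries left out in turn gave 0.553 to 0.687. The difference between the responses was tested directly. Among the 5 genes with the smallest p were Ehhadh (2.05 ± 0.371), Plin2_2 (1.69) and Lin28b (1.91), an RNA-binding repressor of microRNA maturation in fetal cells, each with an adjusted p of 0.0992. The limma test called 0 of 11798 genes, with 2343 at an unadjusted p under 0.05. It called 421 without Cpt2LKODam_FloxFetus replicate 4, of which 343 were higher for the Ppara dams, 2 without HetDam_HetFetus replicate 1, and 1 each without HetDam_HetFetus replicate 4, KODam_HetFetus replicates 1 or 3 or FloxDam_FloxFetus replicate 2. Adding the number of genes with a value as a covariate gave 115, of which 34 were higher and 81 lower.

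**Figure D3:**
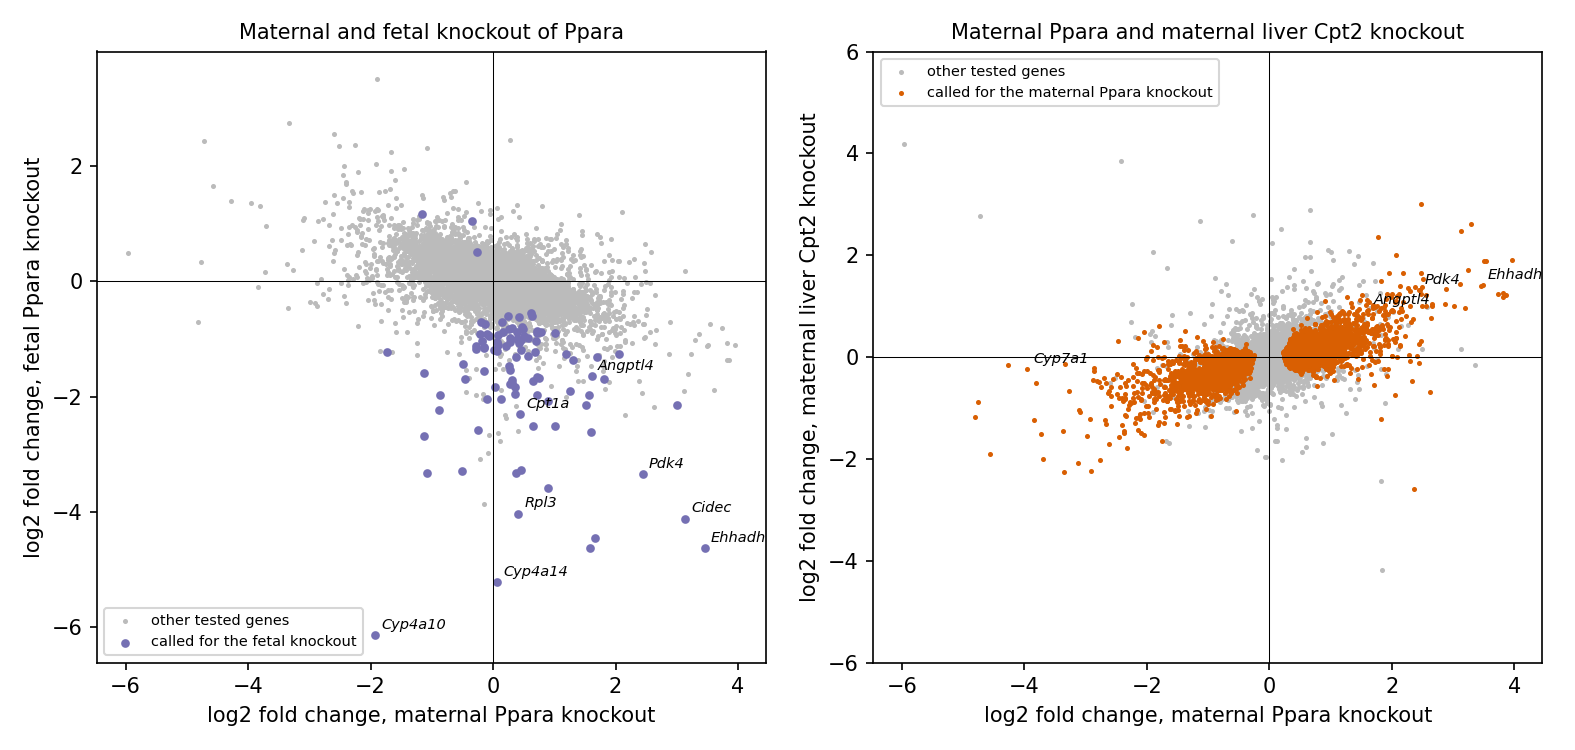
Log2 fold changes of the tested genes, with 1 point per gene: fetal against maternal Ppara knockout on the left, and maternal liver Cpt2 against maternal Ppara knockout on the right. Colored points were called for the fetal knockout (left, 97 genes) or the maternal Ppara knockout (right, 4600 genes); r is -0.517 on the left, where the comparisons share libraries, and 0.628 on the right.

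The control groups of the arms were compared to show how far the backgrounds of HetDam_HetFetus and FloxDam_FloxFetus differ. Mcpt8 (chromosome 14, 56082163 to 56085499, GRCm38.p6), a basophil protease, fell by 3.21 ± 0.467 on the log2 scale in HetDam_HetFetus relative to FloxDam_FloxFetus (limma adjusted p = 0.00209), and Cd59b, a complement inhibitor, fell by 2.60 ± 0.375 (adjusted p = 0.00209). The ribosomal protein gene Rpl3 (chromosome 15, 80077781 to 80083406, GRCm38.p6) fell by 1.41 ± 0.131 (adjusted p = 9.02e-06), and its processed copy Rpl3-ps1, chosen after its values were seen, rose by 5.70 ± 0.224 (adjusted p = 4.09e-12). Rpl3 also fell with the fetal Ppara knockout, by 4.04 ± 0.131 (adjusted p = 1.14e-13). Reads of Rpl3 and Rpl3-ps1 may be split between the copies, so their separate values are uncertain. Of 6 mast cell and basophil genes 1 fell, or 3 adjusted over the list alone (camera adjusted p = 0.00343, adjusted p = 0.296 with an estimated correlation), and 0 did without the 4 libraries with marker transcripts of other tissues. The 34 hepatocyte genes had a median of 0.26 with 0 calls, or 0.41 after trimmed-mean scaling, 0.05 without FloxDam_FloxFetus replicate 1 and 0.42 without its replicate 3 (camera adjusted p = 2.60e-09, adjusted p = 0.33 with an estimated correlation). Of 17 lists called by camera 16 ran higher than the other genes, those of several blood and vessel cell types included, but 0 were called with an estimated correlation and 1 with fry, where 3 ran the other way. In all 16 genes were called, 7 higher and 9 lower. The median of all genes was -0.15 as deposited and -0.00156 after trimmed-mean scaling, which gave 10 higher and 6 lower (62.5% against 43.8%), and quantile normalization gave 9 and 3. The count was 35 without HetDam_HetFetus replicate 1, 9 without its replicate 3 or 4 and 8 without FloxDam_FloxFetus replicate 1.

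**Figure D4:**
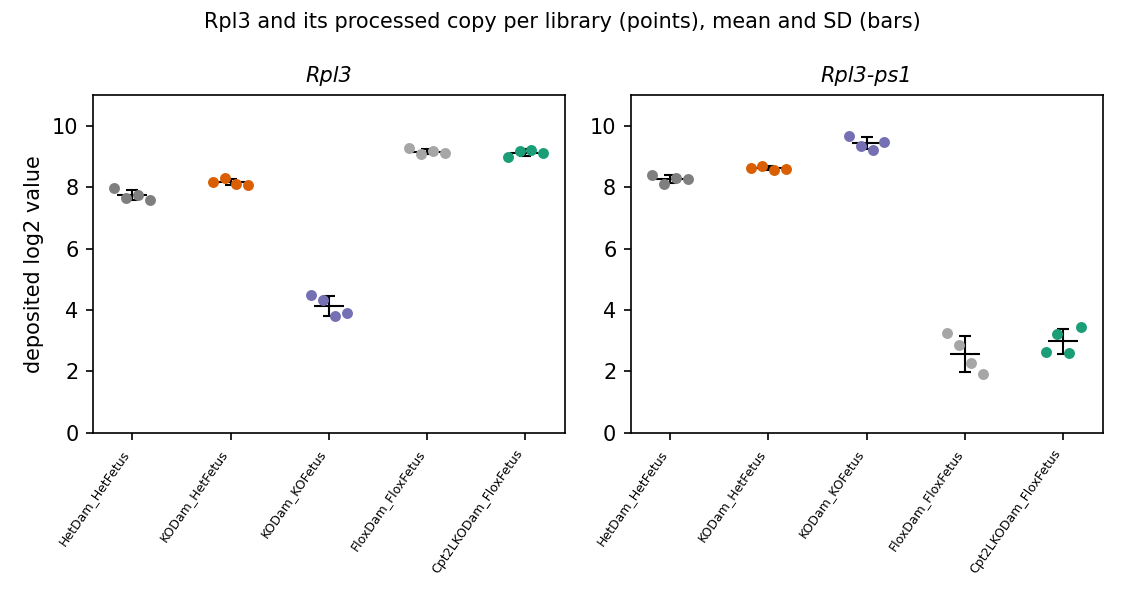
Deposited log2 values (y axes) of Rpl3 (left) and its processed copy Rpl3-ps1 (right) in the 5 groups, with 1 point per library and bars for the mean and SD of 4. Rpl3 averages 4.12 in KODam_KOFetus and 9.15 in FloxDam_FloxFetus, and Rpl3-ps1 averages 9.43 and 2.58.

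Male and female fetuses, 10 of each, differed in 6 of 11807 genes, 3 higher and 3 lower in males. Xist (chromosome X, 103460373 to 103483233, GRCm38.p6), the RNA of X inactivation, fell by 8.83 ± 0.287 on the log2 scale (limma adjusted p = 5.38e-13), and the X-linked genes Kdm6a and Eif2s3x, which escape inactivation, fell by 1.13 ± 0.151 and 0.59 ± 0.0853. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d rose by 8.45 ± 0.313, 7.41 ± 0.398 and 6.78 ± 0.395, with a value in 10, 6 and 8 of the 10 female libraries. Uty did not reach the expression minimum. The sex labels matched Xist and the Y-linked genes in all 20 libraries.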

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

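The tests of the 3 patterns weighed here were chosen only after the results were seen. Single libraries stood apart from the other 3 of their group in 13 of 272 groups of values examined, where chance gives about 1 in 20 groups, or 14. For each, the ratio is the gap to the nearest library over the range of the group. In KODam_HetFetus these were Pdk4 in replicate 3 (log2 value 5.79 against 6.84 for the nearest library, ratio 0.877), Ehhadh in replicate 4 (7.71 against 7.04, 0.95), and Abcb4 (4.49 against 4.76, 0.883) and Hmox1 (6.76 against 6.91, 0.854) in replicate 2. In HetDam_HetFetus they were Acot1 (3.03 against 4.41, 0.835) and Acot2 (0.79 against 1.84, 0.861) in replicate 4, Hsd17b6 in replicate 1 (0.27 against 0.92, 0.889), Per1 in replicate 3 (3.19 against 2.65, 0.996) and Acads in replicate 2 (5.22 against 5.38, 0.89). In KODam_KOFetus, replicate 2 stood high for Etfb (ratio 0.886), Plin5 (1.89 against 0.25, 0.92), the mean of the peroxisomal and microsomal fatty acid oxidation list (-0.88 against -1.44, 0.885) and that of the lipid droplet list (-0.43 against -0.63, 0.883). Between the maternal knockouts of Ppara and Cpt2, 14 lists differed by the camera test of the difference itself, where the median of all genes was 0.149 as deposited. The smallest adjusted p-values were those of neutrophil and myeloid progenitor genes (median -0.658, adjusted p = 2.89e-12), cell cycle genes (0.647, adjusted p = 1.02e-07) and hepatocyte genes (-0.328, adjusted p = 1.02e-07), whose medians were -0.39, 0.38 and -0.11 without replicates 1 and 2 of KODam_HetFetus. The other medians, each followed by its value without that pair, were -0.478 (-0.11) for gluconeogenesis and fasting response, -0.604 (-0.28) for bile acid synthesis and transport, -0.102 (-0.01) for oxidative phosphorylation, -0.615 (-0.21) for acute phase, -0.766 (-0.11) for interferon response, 0.442 (0.24) for erythroid, -0.211 (-0.24) for megakaryocyte and platelet, -0.346 (-0.18) for B lymphoid, -0.152 (-0.02) for macrophage, -0.0529 (-0.03) for endothelial and -0.664 (-0.29) for cholangiocyte genes. The hepatocyte median was -0.17 without FloxDam_FloxFetus replicate 1, and those of the megakaryocyte and endothelial lists turned positive without single libraries (at most 0.0955 and 0.101). With an estimated correlation the adjusted p was 0.801 for the erythroid and megakaryocyte lists and 0.611 for the other 12.

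The first pattern is the exchange between Rpl3 and Rpl3-ps1, which stood at 4.12 ± 0.332 and 9.43 ± 0.197 (SD, n = 4) in KODam_KOFetus and at 9.15 ± 0.0906 and 2.58 ± 0.595 in FloxDam_FloxFetus. Regulation by fetal PPARA is argued against, since Rpl3-ps1 differed by 5.70 between the control groups while the canonical PPARA targets differed there by -0.17 in median. The sum of both genes differed by 0.296 on the log2 scale between KODam_KOFetus and FloxDam_FloxFetus, which is consistent with reads of one gene being assigned to its copy. A stretch of another strain carried along with the null allele could give such an assignment, since Rpl3 and Ppara lie on the same chromosome, and 2 of 197 tested genes within 10 Mb of Ppara were called for the fetal knockout against 66 of 10987 elsewhere (two-sided Fisher's exact p = 0.337). A first version of this test kept genes that overlap PPARA targets and gave 4 calls near Ppara with an exact p of 0.0358. Those genes were then left out, and with so few calls this test cannot tell a linked strain segment from its absence. The 2 calls were Apobec3 (-1.44) and Dennd6b (-0.80), which differed by -0.86 and -0.31 between the control groups without a call. Rpl3 averaged 7.745 and 8.16 in HetDam_HetFetus and KODam_HetFetus, and Rpl3-ps1 8.27 and 8.62. Both genes were thus ordered by the number of null alleles, as a linked segment would make them, but the segment itself was not examined.

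The second pattern is the breadth of the maternal Ppara change, 4600 genes with 67.8% of them higher, where trimmed-mean scaling left 4444 calls and leaving out replicates 1 and 2 of KODam_HetFetus left 2845, which argues against the scaling or that presumed litter alone as the source of the breadth. The share of higher calls was 49.8% after that scaling, but centring brought the median change of all genes to 0.0168 and removes such a shift whatever its source. The median deviation of the 20 libraries went with their number of genes with a value (r = 0.964), and with that number as a covariate the share was 54.2%, so the deposited scaling may have given part of the excess, but the number may itself follow the groups, and a real excess and one from the scaling cannot be told apart. The neutrophil list minus the endothelial list differed by -0.777 between KODam_HetFetus and HetDam_HetFetus (SD 0.269 and 0.249, n = 4, two-sided exact permutation p = 0.0286, the smallest possible). The neutrophil markers thus fell more than the endothelial ones. The lists were picked after the fall was seen in these libraries, and presumed littermates counted as independent. The value therefore does not decide whether a single cell type diluted all other cells equally. A response of the fetal liver to the knockout dam and separate shifts of several cell types stay open, and neither was tested.

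The third pattern is Cpt2LKODam_FloxFetus replicate 4, whose deviation from the Cpt2-arm control correlated across genes with the maternal Ppara effect at r = 0.768, against 0.301, 0.14 and 0.497 for replicates 1 to 3. A library of the Ppara arm under this label is argued against, since its Rpl3-ps1 value was 3.45, where the heterozygous groups averaged 8.27 and 8.62. Its 25326 genes with a value lay within the range of the other 3 of its group (24231 to 25764), and its highest marker list of pancreas, muscle or gut deviated by 0.409 from the mean of all libraries. By these measures the library did not stand out in genes detected or in carry-over of these tissues. Whether either contributes to the correlation was not tested. A stronger response in this fetus or its litter remains a candidate explanation, which a single fetus cannot separate from a difference in dissection or fasting.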

How the results depend on the processing

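The settings that leave out named libraries together or add the number of genes with a value were chosen only after the results were seen. No named gene that was called reversed its direction. The medians of the megakaryocyte and endothelial lists for the difference of the maternal effects turned positive without single libraries (at most 0.0955 and 0.101), 3 lists called between the control groups ran the other way with fry, and the share of higher calls went from 70.4% to 45.4% for both knockouts and from 43.8% to 62.5% between the control groups after trimmed-mean scaling. Of the compared values 3838 were labelled unchanged. For genes and lists this means the same side of the threshold, with the direction compared only where there was a call. For counts it means staying within a set ratio. A further 213 values lost a call, 32 gained one, and 41 counts or correlations moved beyond that ratio or away from 0. For the maternal Ppara knockout (4600 genes) the littermate pair left out gave 2845 calls, and single libraries left out gave 3536 to 4215. For the fetal knockout (97) fitting only the groups compared gave 63, and single libraries left out gave 75 to 147. For both knockouts (2916) leaving out the 4 libraries with markers of other tissues gave 1757, and single libraries 1828 to 3024. For the maternal Cpt2 knockout (0) quantile normalization gave 1 and single libraries left out 0 to 1. For the difference of the maternal effects (0) a pseudocount of 4 gave 2, the 4 libraries left out 1, the littermate pair left out 1, the number of genes with a value as a covariate 115, and single libraries left out 0 to 421. For the control groups (16) the stricter filter gave 5, a pseudocount of 4 gave 7, no mean-variance trend 26, the litter as a random block 8, littermates averaged 9, and single libraries left out 8 to 35. Leaving out single libraries ended calls of Acadm and Mchr1 for the maternal Ppara knockout, of Acot1, Ank, Clec4a1, Cpt2, Hmox1 and Slc16a7 for the fetal knockout, of Acot1, Cpt2, Gh, Ppara, Samd15, Snord16a and Wfikkn1 for both, and of Cep78 and Cmss1 between the control groups. The stricter filter tested fewer genes and the omissions fewer samples, and for the others the cause was not tested. With an estimated correlation and with fry, the lists called were 0 and 4 for the maternal Ppara knockout (14 with the preset correlation), 5 and 6 for the fetal knockout (13), 0 and 9 for both (22), 0 and 0 for the maternal Cpt2 knockout (7), 0 and 0 for the difference (14), 0 and 1 for the control groups (17), and 0 and 0 for sex (12). The correlation of the maternal effects ran from 0.421 to 0.687 with single libraries left out, and was 0.801 over 4571 called genes. These genes were selected by their calls in the same data, and relabelled libraries reached an absolute r of 0.797 over them. The higher value is therefore no sign of a closer likeness. Outside the control groups, not every same-numbered pair of libraries deviated together. Their correlations ran from -0.228 to -0.0814, -0.378 to 0.172, -0.208 to 0.269 and -0.0164 to 0.211 for the first 4 comparisons, with 0, 1, 1 and 2 of 4 pairs over 0.1 and 0, 0, 2 and 1 best with their own number. The replicate block gave 4681, 102, 3050, 0 and 0 calls for the first 5 comparisons, 15 for the control groups and 5 for sex. A count test was not run, as the reads cannot be recovered. The unknown depth limits what can be said of genes with low values.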

Other observations

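The tests of other splits of the samples were planned, and the marker lists of neighbouring tissues were compared only after the libraries had been seen. Further gene groups differed in fetuses of Ppara knockout dams. Of 20 acute phase genes, 8 fell and 1 rose relative to HetDam_HetFetus, with the same counts adjusted over the list alone and a median of -0.69 (camera adjusted p = 3.61e-04, adjusted p = 0.732 with an estimated correlation). Without the presumed littermates, replicates 1 and 2 of KODam_HetFetus, 3 fell and the median was -0.18, and 5 fell without replicate 1 alone. Of 18 interferon response genes 6 fell and 0 rose, also when adjusted over the list alone (median -0.84, camera adjusted p = 8.90e-04, adjusted p = 0.732 with an estimated correlation). Without the same pair 0 fell and the median was -0.19, 1 fell without the 4 libraries with marker transcripts of other tissues, 3 without HetDam_HetFetus replicate 1 or KODam_HetFetus replicate 1 or 2, and 11 without KODam_HetFetus replicate 4. Of 25 genes of cholesterol synthesis 8 fell and 1 rose, or 7 and 1 adjusted over the list alone (median -0.31, camera adjusted p = 0.00127, adjusted p = 0.732 with an estimated correlation), with 5 falls without the pair, 2 without the 4 libraries, and 4 to 9 with single libraries left out (4 without KODam_HetFetus replicate 1). In the maternal liver Cpt2 knockout the cholesterol genes had a median of -0.31 as well, with 0 calls by either adjustment (camera adjusted p = 5.30e-05, adjusted p = 0.883 with an estimated correlation), and a median of -0.15 without FloxDam_FloxFetus replicate 1.

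Knockout fetuses of knockout dams also differed from HetDam_HetFetus in lists other than those of erythroid, hepatocyte and fatty acid oxidation genes, and of the 22 lists called by camera 20 ran lower and 2 higher than the other genes, of which 0 were called with an estimated correlation and 8 with fry. Of 12 bile acid genes 6 fell and 0 rose, or 7 adjusted over the list alone (median -1.01, camera adjusted p = 3.36e-04, adjusted p = 0.438 with an estimated correlation), and 3 fell without KODam_KOFetus replicate 1 or 4. Of 32 cell cycle genes 22 rose and 0 fell, or 24 adjusted over the list alone (median 0.62, camera adjusted p = 7.13e-08, adjusted p = 0.438 with an estimated correlation), and of 23 neutrophil and myeloid progenitor genes 12 fell and 0 rose, or 13 adjusted over the list alone (median -0.65, camera adjusted p = 4.71e-09, adjusted p = 0.438 with an estimated correlation). Single libraries left out gave 12 to 22 cell cycle rises, with 11 after trimmed-mean scaling, and 3 to 16 neutrophil falls. The fewest cell cycle rises came without KODam_KOFetus replicate 1, and the fewest neutrophil falls without its replicate 4. The 94 genes that fell with the fetal knockout had a median of 0.19 for the maternal Cpt2 knockout, which shares no library with that comparison, and 68 of 94 were positive there.

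Some libraries carried marker transcripts of neighbouring tissues above the mean of all libraries. Skeletal muscle genes (5) deviated by 3.54 on the log2 scale in HetDam_HetFetus replicate 4 and by 3.98 in KODam_KOFetus replicate 2, pancreatic acinar genes (3) by 3.49 in Cpt2LKODam_FloxFetus replicate 2, and gut genes (3) by 2.68 in HetDam_HetFetus replicate 1.

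Other splits of the same samples show how often a regrouping gives as many genes called by limma. For the maternal Ppara knockout 1 of 35 splits, the real one, gave as many as 4600, and the highest other gave 11. For both knockouts 1 of 35 gave as many as 2916, with 1 for the highest other. For sex 1 of 100 splits drawn gave as many as 6, with 2 for the highest other. In these 3 comparisons no other split reached the real count. The splits treat presumed littermates as independent, so they do not exclude a difference between litters. A large difference between groups also widens the spread within mixed splits, which lowers their counts. For the fetal knockout 3 of 35 splits gave as many as 97, with 192 for the highest other, so chance is not excluded. A split with 117 calls followed the presumed litters, and the fit with litter as a block called 71 for the real groups. For the maternal Cpt2 knockout, with 0 calls, all 35 of 35 gave as many and 1 gave 476. For the difference of the maternal effects, also 0, it was 100 of 100 with a highest of 2587, and for the control groups 2 of 35 gave as many as 16, with 801 for the highest other. The splits with 476 and 801 calls part replicates 1 and 2 from replicates 3 and 4 of both groups, which may point to a structure of these samples other than their groups. Both splits divide the same FloxDam_FloxFetus libraries, whose replicates 3 and 4 are presumed littermates, so they are not independent signs of such a structure. In the control groups all 4 same-numbered pairs of libraries deviated together, which does not establish a pairing, and the replicate block gave 15 calls. The real split was 1 of 8 that part all 4 pairs, and the highest of the other 7 gave 1. So few splits cannot exclude chance.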
